A study of Ovis aries with 10 samples.

How the data were processed

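The data were counts of reads per gene from 10 RNA sequencing libraries of ewe mediobasal hypothalamus, 5 of the follicular and 5 of the luteal phase. Per the labels' protocols, RNA was extracted with TriReagent and libraries were made with a TruSeq stranded mRNA kit. Per the series' design text, each library was an equimolar mix of RNA of 2 ewes drawn at random within a phase, from 20 ewes in all, so the p-values measure the spread between mixes of separate animals. The submitters' processing notes name bcl2fastq 2.20, FastQC, TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 1.9 and featureCounts 2.0.0, without their order or settings. The genome build, the strand setting, the treatment of reads that map to several genes and any filter were not given in the sources used here.

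The authors deposited whole-number counts per gene, not normalised, in 1 table with a column for each of the 10 libraries. The table held 33775 genes with numeric gene identifiers. Of these identifiers 31873 (94.4%), with 99.4% of all counts, matched the gene table of assembly ARS-UI_Ramb_v3.0, which was used for names only, and 492 symbols were taken from it. For 22 genes no symbol was held; they kept their identifiers and stayed in the totals, with at most 0.000291% of a library's count. The identifier listed as FAM189A1 is named ENTREP2 in that assembly, and LOC114117494 and LOC105608589 are not named in it. Since the strand setting and the handling of shared reads are not known, values of genes that overlap on opposite strands or have near-identical copies are uncertain. This concerns the ribosomal protein genes, which have many processed copies, and AVP and OXT, which share a closely similar exon.

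Counts were analysed in R 4.3.3. The test was the quasi-likelihood F-test of edgeR 4.0.16, two-sided, without robust estimation, on all 10 libraries with phase as the only term, after filterByExpr by phase (minimum count 10, minimum total 15) and TMM scaling, which left 18276 genes. Fold changes are luteal over follicular, with their standard errors, and p-values were adjusted by Benjamini-Hochberg over the genes tested with a threshold of 0.05. CPM values are a gene's reads relative to the library's TMM-scaled total and are given as mean ± SD over 5 libraries. The biological coefficient of variation was 25.1%.

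A total of 41 gene lists for biology, RNA quality, cell types and regions was fixed before the data were examined, as were the rule for named genes, the tests and most of the alternative settings. Of 655 distinct list members 626 were matched. The 40 lists with at least 3 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, the red blood cell list having too few, and again with an estimated correlation and with fry, a rotation test of the list alone. For each list the members past the threshold were counted over all genes and adjusted over the list alone. TUBB3 was left out because its name matched only as a synonym of another gene. Differences between phases in library measures and list scores were tested with two-sided exact permutation tests over all 252 assignments of 5 and 5 libraries, where the smallest p possible is 0.00794. Scores used log2 CPM with a prior count of 2.

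Named genes were chosen as follows. Where fewer than 5 genes in a direction passed edgeR, the 5 with the smallest p were named. Each list called by camera gave up to 4 members with the smallest p and each other biology list up to 2. A fixed set was named always: PGR, ESR1, KISS1, TAC3, PDYN, GNRH1, POMC, NPY, AGRP, TH, AVP, OXT, PRLR, DIO2 and DIO3. Other members are named where they passed adjusted over their list alone, and genes beyond these that DESeq2 called were chosen after their values were seen. The result of 1 gene is not reported here.

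Every pair of libraries was compared by a chi-square test over genes with at least 10 reads, and no pair agreed within sampling noise, so all 10 were counted as separate. The alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 5 libraries, the replicate number in the model, leaving out each library, limma-voom, voom with quality weights, DESeq2 1.42.0, robust dispersion, 1 surrogate variable from sva 3.50.0, a threshold of 0.10 and a fold change of at least 1.5. Added after seeing the data were the first principal component as a covariate, thinning of every library to the smallest total, and leaving out follicular 1 and 3 together.

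The tests were checked on simulated counts drawn from the libraries' means and totals, with 200 genes changed and the endoplasmic reticulum stress list shifted lower. Each gene was drawn independently, without an axis shared by many genes such as the real libraries have. The rates below therefore need not hold for the real counts. Over 18147 genes edgeR recovered 5% of the genes changed by 1.5-fold and 43% of those changed by 2-fold, with 5.8% of its calls on unchanged genes. DESeq2 recovered 28% and 74%, with 28.9% of its calls on unchanged genes, and limma-voom 5% and 39%, with 6.2%. With no gene changed, over 18136 genes, edgeR and limma-voom called 0 and DESeq2 10.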

Results

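Gene-level read counts were measured by RNA sequencing of the mediobasal hypothalamus, the ventral part of the hypothalamus that holds the arcuate nucleus and the median eminence, of adult Ile-de-France ewes. RNA came from 20 ewes, 10 in the follicular and 10 in the luteal phase of the ovarian cycle. Within each phase RNA was combined at random into 5 equimolar mixes of 2 ewes each, so that each phase had 5 libraries and no ewe contributed to both phases. The count table held 33775 genes. Library totals ran from 20644992 to 43193449 reads. Follicular libraries 1 to 5 held 21092056, 27292984, 20644992, 28669577 and 43193449 reads, and luteal libraries 1 to 5 held 40768886, 37206726, 28571863, 42358557 and 39073442 reads. The mean was 28178600 ± 9130240 reads in follicular and 37595900 ± 5397190 reads in luteal libraries (SD, n = 5 per phase; two-sided exact permutation test, p = 0.111, adjusted p = 0.25 over 7 library measures). The number of genes with at least 1 read averaged 22082 in follicular and 22670 in luteal libraries (exact permutation test, p = 0.0397, adjusted p = 0.25).

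The series title asks how progesterone acts on the transcriptome of this region, and the single comparison the design gives is luteal against follicular phase. The genes with the smallest p were, higher in luteal libraries, TNC, FSTL4, CORIN, NOTCH3 and LOC101104530, and, lower in luteal libraries, LOC114117494, CPLX2, LOC105608589, FAM189A1 and TRH. TNC, which encodes the matrix glycoprotein tenascin C, averaged 37.3 ± 5.20 CPM (scaled read counts) in follicular and 59.8 ± 7.74 CPM in luteal libraries (SD, n = 5 per phase). CORIN, a membrane serine protease that processes natriuretic peptide precursors, averaged 26.3 ± 3.65 and 46.4 ± 9.39 CPM, and NOTCH3, a receptor found on vascular mural cells, 79.9 ± 4.63 and 107.6 ± 7.73 CPM. CPLX2, which encodes the presynaptic protein complexin 2, averaged 227.6 ± 25.5 CPM in follicular and 154.9 ± 20.9 CPM in luteal libraries. TRH, the precursor of thyrotropin-releasing hormone, averaged 18.4 ± 3.76 and 10.5 ± 1.95 CPM.

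None of these genes passed the edgeR quasi-likelihood test after adjustment over the 18276 genes tested. The smallest adjusted p was 0.426, shared by the 10 genes named above, and edgeR called 0 genes. Unadjusted p was under 0.05 for 2083 genes, of which 781 were higher and 1302 lower in luteal libraries. By the other tools limma-voom called 0 genes, DESeq2 called 29 (14 higher and 15 lower in luteal) and voom with quality weights, which gives libraries unequal weight, called 5867. The log2 fold changes of luteal over follicular by edgeR were 0.68 (SE 0.12) for TNC, 0.52 (SE 0.10) for FSTL4, 0.82 (SE 0.15) for CORIN, 0.43 (SE 0.08) for NOTCH3 and 0.42 (SE 0.09) for LOC101104530. In the other direction they were -1.34 (SE 0.22) for LOC114117494, -0.56 (SE 0.12) for CPLX2, -1.29 (SE 0.27) for LOC105608589, -1.78 (SE 0.39) for FAM189A1 and -0.80 (SE 0.18) for TRH. All 10 were among the 29 genes called by DESeq2, with the smallest DESeq2 adjusted p at 6.0e-05 for LOC114117494. Apart from LOC105608589, the 5 luteal values of each of these genes lay entirely on one side of the 5 follicular values. Over all genes tested this separation held for 205, or 1.1%, where chance gives 0.79%. Camera called 7 of the 40 preset gene lists at its preset correlation, 0 with an estimated correlation, and fry called 0. Of 100 splits of the 10 libraries into 5 and 5, 15 gave at least 29 genes by DESeq2 and 60 gave at least 7 lists by camera.

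**Figure D1:**
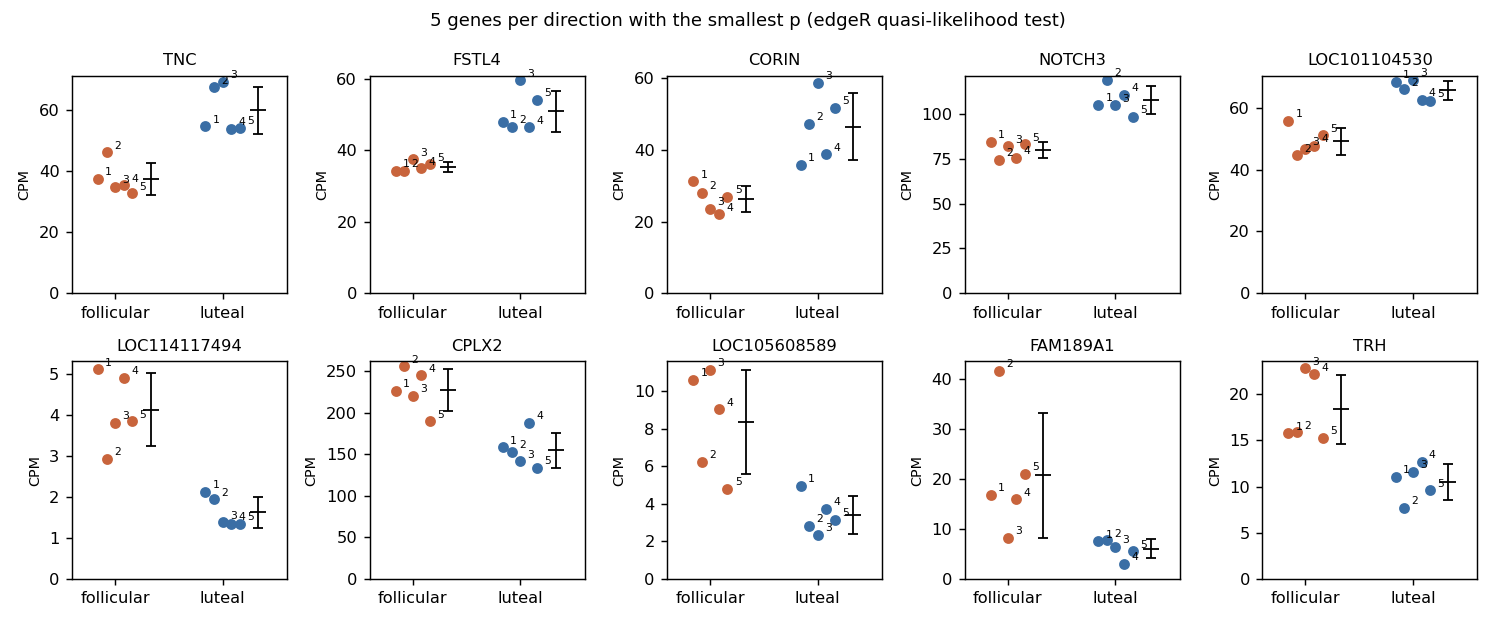
CPM of the 5 genes per direction with the smallest p, one point per library (n = 5 per phase, numbered by replicate), with the phase mean ± SD as a black bar. TNC lies at 32.7 to 46.1 CPM in follicular and 53.9 to 69.2 CPM in luteal libraries, and none of the 10 genes passed the edgeR test after adjustment.

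VGF, OXT and AVP averaged lower in luteal libraries without passing edgeR over all genes, and DESeq2 called VGF (adjusted p = 0.0332) and OXT (0.0423) but not AVP (0.307). VGF, the precursor of several secreted neuropeptides, averaged 1285 ± 182 CPM in follicular and 564 ± 315 CPM in luteal libraries (SD, n = 5 per phase; log2 fold change -1.19, SE 0.28). OXT, the oxytocin precursor, averaged 84.9 ± 39.9 and 26.0 ± 13.5 CPM (log2 fold change -1.70, SE 0.45), and AVP, the vasopressin precursor, 1110 ± 765 and 330 ± 236 CPM (log2 fold change -1.75, SE 0.66). The preset list of neurohypophysial and releasing hormones and their receptors was called lower in luteal by camera (adjusted p = 0.00533 over 40 lists), and this call was lost with adjusted p = 0.54 with an estimated correlation and adjusted p = 0.109 by fry, and with quality weights (adjusted p = 0.106). Of its 14 tested members 8 were lower and 6 higher, with a median log2 fold change of -0.23. Over all genes 0 members passed edgeR, and adjusted over the list alone 3 fell: TRH (edgeR adjusted p = 0.00897), VGF (0.00897) and OXT (0.0115).

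One luteal library stood apart in VGF. Luteal 4 had 1122 CPM, inside the follicular range of 1035 to 1493 CPM, and the other luteal libraries had 369 to 479 CPM. Without luteal 4, VGF was the single gene that edgeR called over all genes (log2 fold change -1.60, adjusted p = 0.00428). Since luteal 4 was the luteal library farthest out in VGF, leaving it out lowers the spread of VGF and is no separate support. With any other single library left out VGF did not pass (edgeR adjusted p from 0.0606 to 0.750). The camera call of the hormone list was lost without follicular 5 (adjusted p = 0.0728). With the first principal component of the libraries as a covariate, an alternative added after the data had been seen, the log2 fold change was -0.52 for AVP, -0.95 for OXT, -0.65 for TRH and -1.11 for VGF. None of these passed over all genes (edgeR adjusted p from 0.325 to 0.839). The hormone list was still called lower by camera at its preset correlation (adjusted p = 0.00395). Without the component that call was lost with an estimated correlation (adjusted p = 0.54) and by fry (0.109), as given above.

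**Figure D2:**
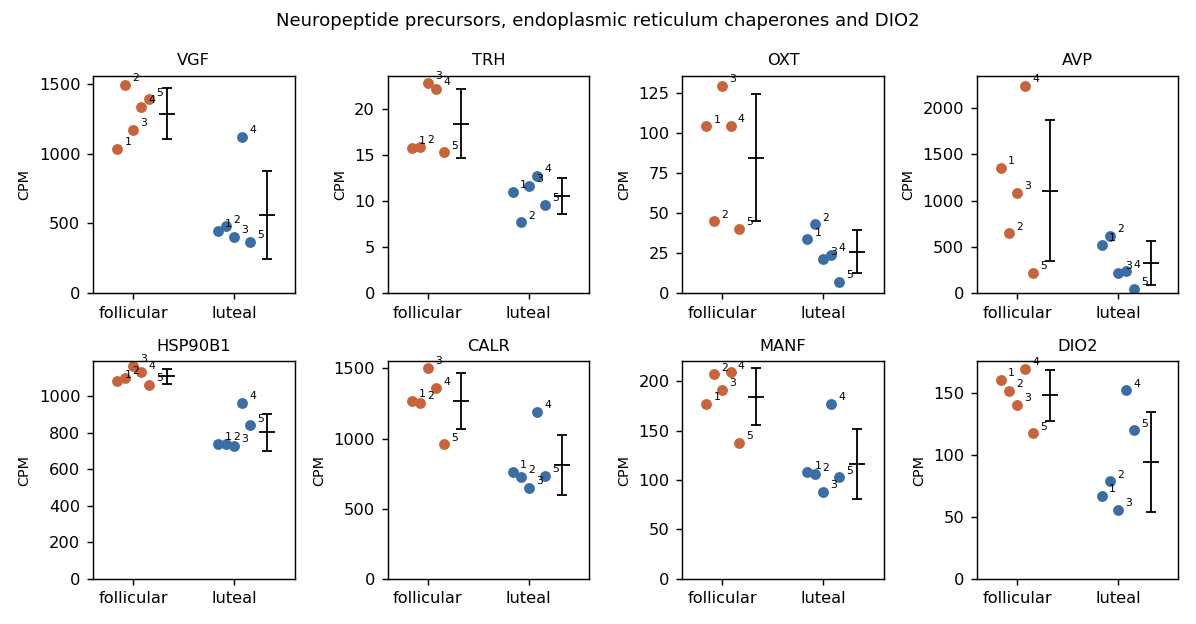
CPM of VGF, TRH, OXT, AVP, HSP90B1, CALR, MANF and DIO2, one point per library (n = 5 per phase, numbered by replicate), with the phase mean ± SD as a black bar. Luteal 4 lies at 1122 CPM for VGF and 1189 CPM for CALR, against at most 479 and 764 CPM in the other luteal libraries.

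Of the chaperones and stress proteins of the endoplasmic reticulum, HSP90B1, CALR, MANF and HSPA5 averaged lower in luteal libraries, and other members such as CANX and DNAJB9 averaged higher. HSP90B1, the endoplasmic reticulum form of HSP90, averaged 1110 ± 41.4 CPM in follicular and 803 ± 102 CPM in luteal libraries (SD, n = 5 per phase; log2 fold change -0.47, SE 0.10). CALR, the calcium-binding chaperone calreticulin, averaged 1269 ± 200 and 813 ± 215 CPM (log2 fold change -0.64, SE 0.18), and MANF, a secreted protein induced by unfolded proteins, 184.5 ± 29.1 and 116.4 ± 35.1 CPM (log2 fold change -0.66, SE 0.19). HSPA5, the main HSP70 of the endoplasmic reticulum, averaged 1109 ± 158 and 807 ± 146 CPM. The endoplasmic reticulum stress list was called lower by camera (adjusted p = 0.000239), with 15 of 20 members lower and a median log2 fold change of -0.27, and the call was lost with adjusted p = 0.72 with an estimated correlation and adjusted p = 0.244 by fry. Over all genes 0 members passed edgeR. Adjusted over the list alone 7 fell: HSP90B1, DNAJB11, CALR, MANF, SDF2L1, HSPA5 and CRELD2, with edgeR adjusted p from 0.0155 to 0.0493. HSP90B1 was also called by DESeq2 (adjusted p = 0.0086).

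The lists of cytosolic ribosomal proteins and of the nuclear-encoded respiratory chain were called lower in luteal by camera, and both calls were lost with adjusted p = 0.72 with an estimated correlation. All 30 ribosomal protein genes were lower (median log2 fold change -0.47; camera adjusted p = 9.5e-08), as were 19 of 20 respiratory chain genes (median -0.38; camera adjusted p = 1.5e-06). Fry gave adjusted p = 0.419 and 0.363. No member of either list passed edgeR over all genes, and 0 passed adjusted over the list alone. RPS24 averaged 1244 ± 513 CPM in follicular and 777 ± 168 CPM in luteal libraries, and COX5A 265.6 ± 91.2 and 171.7 ± 39.8 CPM (SD, n = 5 per phase). The listed ribosomal protein genes took 4.07% of the count in follicular 1, 2.84% in follicular 2, 4.07% in follicular 3, 3.70% in follicular 4 and 2.26% in follicular 5, against 2.33% to 3.35% in luteal libraries (exact permutation test of the means, p = 0.198, adjusted p = 0.278). This share followed the first principal component of the libraries, which held 51% of the variance. Follicular 2 (-1.96) and follicular 5 (48.1) both lay within the luteal range of -14.4 to 58.2 on it. With that component as a covariate the ribosomal protein list was higher in luteal without passing (camera adjusted p = 0.0803) and the respiratory chain list was lower without passing (0.364). The scores of these lists followed the component almost fully (r = -0.983 and -0.997). A fit with it as a covariate thus takes out most of their variation and is no test of phase. Follicular 1 and 3 were the shallowest libraries and those with the highest ribosomal protein shares. Without them the ribosomal protein list was lower without passing (median -0.18, camera adjusted p = 0.0537). The respiratory chain list was still called lower (median -0.19, camera adjusted p = 0.00233).

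**Figure D3:**
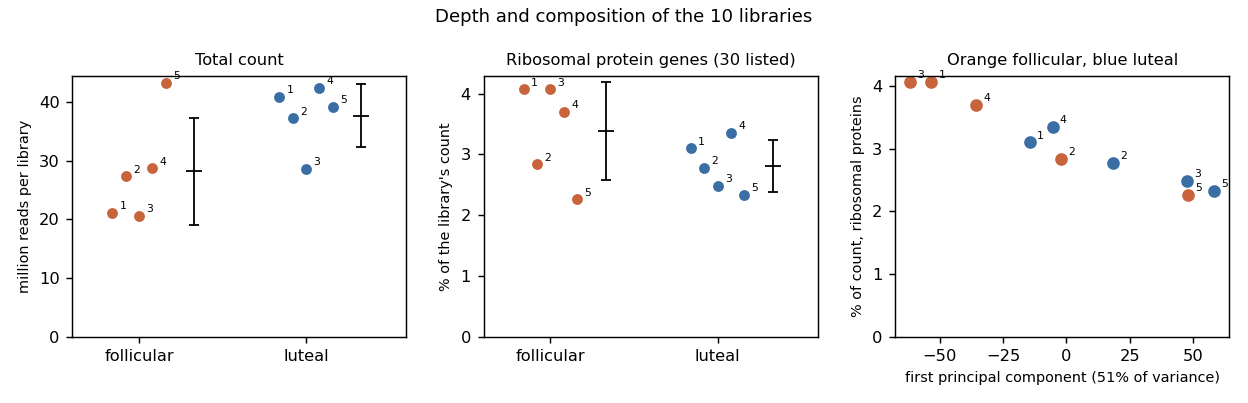
Left, total count of reads per library; middle, share of the count on the 30 listed ribosomal protein genes; right, that share against the first principal component (51% of variance), one point per library, orange follicular and blue luteal, with mean ± SD bars at left and middle (n = 5 per phase). Follicular 1, 3 and 4 have shares of 3.70% to 4.07% and follicular 5 has 2.26%, below every luteal library.

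Choroid plexus markers, immediate early genes and steroid receptors with their coregulators were called higher in luteal by camera, and all 3 calls were lost with adjusted p = 0.72 with an estimated correlation. All 9 tested choroid plexus markers were higher (median log2 fold change 0.58; camera adjusted p = 0.0133), among them SLC4A5, a bicarbonate transporter, at 1.20 ± 0.51 CPM in follicular and 2.61 ± 0.42 CPM in luteal libraries, and AQP1, a water channel, at 2.82 ± 2.63 and 5.76 ± 1.70 CPM. Of 22 immediate early genes 18 were higher (median 0.27; camera adjusted p = 0.0169). NPAS4, a neuronal transcription factor induced by activity, averaged 5.42 ± 1.49 and 8.28 ± 2.53 CPM, and FOSL1, one of the 4 lower members, 2.54 ± 0.57 and 1.44 ± 0.65 CPM. Of 18 steroid receptor and coregulator genes 15 were higher (median 0.18; camera adjusted p = 0.0289), with NR3C2, the mineralocorticoid receptor, at 20.3 ± 3.00 and 28.1 ± 4.34 CPM. By fry they were lost with adjusted p = 0.257, 0.419 and 0.363. No member of these lists passed edgeR over all genes, and adjusted over the list alone 1 rose, SLC4A5 (edgeR adjusted p = 0.0229). The choroid plexus call was lost by camera without luteal 4 (adjusted p = 0.126), with quality weights (0.106), with the first principal component as a covariate (0.0559) and without follicular 1 and 3 (0.0537). The steroid receptor call was lost without follicular 1 (0.0607), with the component (0.717) and without follicular 1 and 3 (0.105). The steroid receptor score followed the component (r = 0.954), so the fit with it is no test of this call. The call of immediate early genes was lost without follicular 3 (0.156), follicular 5 (0.197), luteal 1 (0.0776) or luteal 4 (0.114), with quality weights (0.0891) and without follicular 1 and 3 (0.572), and kept with the component (0.0268).

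Genes of the reproductive axis differed by less than the test could separate. PGR, the progesterone receptor, averaged 1.96 ± 0.28 CPM in follicular and 2.90 ± 0.94 CPM in luteal libraries (SD, n = 5 per phase; log2 fold change 0.56, SE 0.24), and ESR1, the oestrogen receptor alpha, 21.3 ± 5.57 and 26.3 ± 5.69 CPM (0.30, SE 0.20). Among genes of the kisspeptin neurons of the arcuate nucleus, KISS1 averaged 29.3 ± 13.8 and 18.4 ± 4.61 CPM (-0.66, SE 0.35), TAC3, the neurokinin B precursor, 256.7 ± 50.0 and 264.8 ± 41.8 CPM (0.04, SE 0.15) and PDYN, the dynorphin precursor, 101.7 ± 12.2 and 74.5 ± 20.8 CPM (-0.45, SE 0.17). GNRH1, the precursor of gonadotropin-releasing hormone, averaged 3.93 ± 1.40 and 3.39 ± 2.01 CPM (-0.21, SE 0.46). The edgeR adjusted p of these genes ran from 0.426 to 0.888. The list of kisspeptin neuron and GnRH control genes had 9 of 13 members lower (camera adjusted p = 0.26) and 0 members passing, over all genes or adjusted over the list alone. PRLR was not analysed here.

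Among the metabolic and seasonal genes, AGRP averaged 126.6 ± 101 CPM in follicular and 66.9 ± 35.2 CPM in luteal libraries (log2 fold change -0.92, SE 0.48), NPY 131.4 ± 56.1 and 100.5 ± 27.1 CPM (-0.39, SE 0.28) and POMC 1060 ± 369 and 903 ± 284 CPM (-0.23, SE 0.30; SD, n = 5 per phase). TH, the rate-limiting enzyme of dopamine synthesis, averaged 59.5 ± 14.5 and 59.5 ± 15.2 CPM. DIO2, which activates thyroid hormone, averaged 148.2 ± 20.3 and 94.7 ± 40.4 CPM (-0.65, SE 0.25), and DIO3, which inactivates it, 1.93 ± 0.81 and 2.93 ± 0.75 CPM (0.58, SE 0.29). None passed edgeR, with adjusted p from 0.426 to 0.997.

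Markers of the cell types and regions that a block of hypothalamus can hold, and the ribosomal protein and mitochondrial lists, were compared as scores per library, the mean over a list's members of log2 CPM centred on all 10 libraries. Of 18 such scores 0 differed between phases after adjustment and 2 did so at an unadjusted exact p under 0.05. The choroid plexus score was 0.66 higher in luteal libraries (exact permutation test, p = 0.0317, adjusted p = 0.393) and the endothelium score 0.13 higher (exact permutation test, p = 0.0476, adjusted p = 0.393). Luteal minus follicular differences were 0.11 for astrocytes, -0.18 for oligodendrocytes, -0.04 for microglia and macrophages and -0.08 for neurons, with exact permutation p from 0.341 to 0.698. For the regional lists the difference was 0.30 for arcuate and ventromedial genes and -0.29 for paraventricular, supraoptic and suprachiasmatic genes, both with exact permutation p = 0.0873 and adjusted p = 0.393. The latter list contains AVP, OXT and TRH, and adjusted over the list alone TRH and OXT fell (edgeR adjusted p = 0.00838 and 0.0148) while 0 of its members passed over all genes.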

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

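The within-phase relation of VGF to the endoplasmic reticulum stress list and the exchange of luteal 4 were chosen after their results had been seen. So were the regional, thinning and ribosomal score tests and the list test with the first principal component. How the regional test, the thinning test and the VGF relation were read was settled after their values were known. The counts over other splits were set beforehand. The test of VGF with that component was set before its own result was known, but after the data had been seen. A library was picked out where its gap to the nearest library of its phase, divided by the phase's range, passed Dixon's 95% limit for 5 samples. This happened in 15 of 248 groups of libraries tested, and chance gives about 1 in 20, or 12.4.

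Of the 15, 5 concerned luteal 4. Its VGF level was 1122 CPM against at most 479 CPM in the other luteal libraries (ratio 0.855), CALR was 1189 against at most 764 CPM (0.787) and MANF 177.5 against at most 107.7 CPM (0.779). Its score was the lowest of the luteal libraries for GABA-A receptor and GABA synthesis genes (0.758) and for the list of polysialylated NCAM, extracellular matrix and plasticity (0.722).

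VGF, CALR and MANF averaged lower in luteal libraries without passing edgeR over all genes, and luteal 4 had the highest luteal levels of VGF, CALR and MANF. The library axis that carries the ribosomal protein genes is argued against as the whole cause of the VGF fold change only. With the first principal component as a covariate the log2 fold change of VGF was -1.11 (SE 0.29), against -1.19 (SE 0.28) without it. VGF did not pass over all genes in that fit either (edgeR adjusted p = 0.325), so no difference beyond the axis is established. The endoplasmic reticulum stress list was then called lower by camera at its preset correlation with adjusted p = 1.4e-10. Without the component the call of that list was lost with an estimated correlation (adjusted p = 0.72) and by fry (0.244). The lowest follicular VGF level, 1034.87 CPM, lay above the highest of luteal 1, 2, 3 and 5, 478.687 CPM. This argues against an exchange of luteal 4 with a follicular library only if VGF marks the phase, which was not established. It rests on VGF alone, a gene for which luteal 4 was picked out. A single wrong label, a mix that held an ewe of another stage, and a biological difference between ewes remain open and untested. Regulation shared by VGF and members of the endoplasmic reticulum stress list may be the link. Deviations of VGF and of the score of that whole list from the phase means correlated over the 10 libraries. Pearson r was 0.81 (exact within-phase permutation p = 0.0443) and Spearman rho was 0.64 (exact within-phase permutation p = 0.0635). Adjusted over these 2 coefficients p was 0.0635, over the threshold, so that the relation stays a hypothesis. Without luteal 4 and luteal 5, the farthest in VGF, r was 0.89. That value kept phase means that included both libraries, so it does not show the relation without luteal 4. Luteal 5 went against the relation, with the lowest VGF level (369 CPM). Its endoplasmic reticulum stress score (-0.05) was higher than those of luteal 1, 2 and 3 (-0.273, -0.202 and -0.194).

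AVP, OXT and TRH averaged lower in luteal libraries without passing edgeR over all genes, and more paraventricular and supraoptic tissue in the follicular blocks is a candidate explanation. The other 9 tested genes of that regional list had a median log2 fold change of 0.051 (bootstrap SE 0.14). That value does not exclude the explanation, because several of these genes are also expressed in the arcuate or suprachiasmatic nucleus. SIM1, a marker of the paraventricular and supraoptic nuclei, had 19 reads in all and was not tested. SIM1 was also a member of the preset list of mammillary, lateral and posterior hypothalamic genes. Dissection and phase cannot be told apart for these 3 genes. The library axis is open as well, since with the first principal component as a covariate AVP moved from -1.75 to -0.52, OXT from -1.70 to -0.95 and TRH from -0.80 to -0.65, while camera at its preset correlation still called the hormone list lower (adjusted p = 0.00395), a call that without the component was lost with an estimated correlation (0.54) and by fry (0.109).

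Camera at its preset correlation called ribosomal protein and respiratory chain genes lower in luteal libraries, but both calls were lost with an estimated correlation (adjusted p = 0.72) and by fry (0.419 and 0.363). Unequal depth stays open: the median log2 fold change of the ribosomal protein list was -0.47 before and after every library was thinned to the smallest total, which keeps proportions and so is no test. Without the shallow follicular 1 and 3 the ribosomal median was -0.18 and its camera call was lost (adjusted p = 0.0537), while the respiratory chain median went from -0.38 to -0.19 and its call at the preset correlation was kept (0.00233). Follicular 1 and 3 also had the highest ribosomal protein shares of all libraries (4.07% each), so leaving them out is no test of depth. An axis of variation among libraries that runs within each phase could account for the lower ribosomal values. The ribosomal protein score ranged more widely among follicular libraries than the phases differed, and its exact permutation p between phases was 0.183. Gene length stays open as a source of this axis and was not tested, since the annotation used for the counts is not known. The score of the mitochondrially encoded genes, a preset quality list, rose along the component (r = 0.84) as the ribosomal protein score fell (r = -0.98). It did not differ between phases (exact permutation p = 0.429). Whether RNA quality or dissection lies behind the axis was not tested, and an effect of phase on the axis is not excluded.

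Other libraries that stood apart are given as values. In follicular libraries NCOA1 was 66.8 CPM in follicular 5 against at most 49.2 CPM (0.776), EGR2 8.21 in follicular 2 against at most 3.33 (0.774), CRY1 14.0 in follicular 5 against at most 6.78 (0.757), S100A9 1.49 in follicular 3 against at most 0.92 (0.715) and AGRP 303 in follicular 3 against at most 112.9 CPM (0.789). In luteal libraries CRYAB was 152.3 CPM in luteal 1 against at most 99.8 CPM (0.75) and POMC 404.6 CPM in luteal 5 against at least 940.1 CPM (0.796). Scores stood apart for oestradiol responsive genes in follicular 3 (0.856), immediate early genes in luteal 3 (0.739) and pars tuberalis and anterior pituitary markers in luteal 1 (0.791), each the lowest of its phase.

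Counts of calls were set against 100 of the 126 ways to split the 10 libraries into 5 and 5. With edgeR the real split gave 0 genes, which allows no comparison since all 100 must give at least 0, and the highest other gave 7043. At an unadjusted p under 0.05 the real split gave 2083 genes, 14 of the 100 gave as many, and the highest other gave 8926. With DESeq2 the real split gave 29, 15 of the 100 gave as many, and the highest other gave 7894. For lists called by camera the real split gave 7, 60 of the 100 gave as many, and the highest other gave 21. Chance cannot be excluded for these 3 counts. Splits that call many more genes than the real one point to a structure of the samples: the edgeR split with 7043 set follicular 1, 3 and 4 with luteal 1 and 4, the libraries at the low end of the first principal component, against the rest.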

How the results depend on the processing

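The first principal component as a covariate, the thinned libraries and leaving out follicular 1 and 3 were chosen after seeing the data; the other alternatives were planned. The count of 0 genes by edgeR held with both other scalings, both other filters, robust dispersion, the component, thinning and leaving out follicular 1 and 3, and limma-voom also gave 0, with 608 to 2515 genes at an unadjusted p under 0.05. DESeq2 called 29 (14 higher, 15 lower in luteal), voom with quality weights 5867 (2793 higher, 3074 lower; weights from 0.237 for follicular 5 to 3.87 for luteal 2), and 1 surrogate variable gave 1 gene, lower, LOC114109090. A threshold of 0.10 and a fold change of at least 1.5 could give only 0, since the smallest adjusted p was 0.426. Leaving out each library gave 0 to 1 genes, the 1 being lower and found without luteal 4, VGF, with 958 genes (without follicular 3) to 6217 (without follicular 5) at an unadjusted p under 0.05. The cause of these differences was not tested.

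Camera called 7 lists, 6 to 9 with other scalings, filters, weights, the component, thinning and single libraries left out, 4 without follicular 1 and 3, 0 with an estimated correlation and 0 by fry. Fry's mixed test, for change in either direction, called 6 lists, each with adjusted p = 0.0437. Of these, endoplasmic reticulum stress and neurohypophysial and releasing hormones were biology lists. The others were region or cell type lists. They were those of paraventricular, supraoptic and suprachiasmatic genes, and of mammillary, lateral and posterior hypothalamic genes. Pars tuberalis and anterior pituitary, and pericytes and smooth muscle, were the remaining ones. The ribosomal protein list turned to higher in luteal with the component (adjusted p = 0.0803), which is no test for this list, since its score followed the component (r = -0.983). A list past the threshold in neither fit was given no direction.

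The replicate numbers were not taken to pair the samples, since same-numbered libraries deviated together with r = 0.36, 0.05, -0.33, 0.28 and 0.63, not all over 0.1, and 3 of 5 correlated best with their own number. With the replicate block edgeR called 0 genes (4512 at an unadjusted p under 0.05) and camera 9 lists, the 7 and those of oligodendrocytes and of arcuate and ventromedial genes.

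None of the named genes that reversed had passed, and no cause was tested. With 1 surrogate variable log2 fold changes were 0.084 for PNOC, 0.039 for HSD17B1, 0.083 for NDUFA6, 0.11 for RPS24, 0.041 for RPS6, 0.044 for RPL27, 0.15 for RPL30, -0.033 for F5, 0.42 for KISS1, 0.35 for GNRH1 and 0.46 for POMC. With the component they were 0.050 for PNOC, 0.027 for RPL30, 0.18 for KISS1, 0.31 for GNRH1 and 0.32 for POMC. TAC3 was -0.072 with quality weights, and TH was -0.0051 with RLE scaling, -0.0073 with the replicate block, -0.0085 with quality weights and -0.0054 by DESeq2. Leaving out single libraries moved TAC3 from -0.031 to 0.13, GNRH1 from -0.51 to 0.062 and TH from -0.087 to 0.12. Of the other values of named genes under alternatives, 1699 kept their direction and side of the threshold and 77 passed it in the same direction. These 77 came only from quality weights, DESeq2 and, for VGF, the fit without luteal 4. Quality weights called 5867 of 18276 genes and DESeq2 29. Thinning left 17464 genes testable against 18276, with 0 called and 2085 against 2083 at an unadjusted p under 0.05.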

Other observations

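The gene descriptions here report preset lists and DESeq2 calls, and the DESeq2 genes were chosen for naming after their values were seen. Oestradiol responsive genes had 3 members that rose adjusted over the list alone: IGFBP5 and IGFBP4, which bind insulin-like growth factors, and NPY1R, a neuropeptide Y receptor, with log2 fold changes of 0.71, 0.87 and 0.53 (edgeR adjusted p = 0.0253, 0.0253 and 0.0414), and 0 passed over all genes. Of the 15 tested members of this list 9 were higher and 6 lower, with a median log2 fold change of 0.08. Its score was higher in luteal libraries (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.159 over 40 lists), and the list was not called by camera (adjusted p = 0.142). The score of neurohypophysial and releasing hormones, lower in luteal libraries, had the same exact permutation p and adjusted p. Vascular mural cell markers NOTCH3 and MCAM rose adjusted over the list alone (edgeR adjusted p = 0.00306 and 0.00723) in a list with 5 members higher and 6 lower, whose median was -0.03 and mean 0.06 (camera adjusted p = 0.471). Of the pars tuberalis and anterior pituitary markers CGA, the common subunit of glycoprotein hormones, fell adjusted over the list alone (edgeR adjusted p = 0.0374). CGA averaged 2033 ± 245 CPM in follicular and 1343 ± 341 CPM in luteal libraries (SD, n = 5 per phase). GRIK3, a kainate receptor subunit, and TNC rose and CRYAB, a small heat shock protein, fell adjusted over their lists alone (edgeR adjusted p = 0.0447, 0.00289 and 0.0395), with 0 passing over all genes.

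Single genes that DESeq2 called higher in luteal libraries include COL4A6, COL27A1 and AOC3. COL4A6 and COL27A1, 2 collagen chains, averaged 17.3 ± 6.10 and 31.6 ± 3.30 CPM, and 29.8 ± 1.58 and 39.3 ± 4.04 CPM, in follicular and luteal libraries (SD, n = 5 per phase; DESeq2 adjusted p = 0.0423 for both). AOC3, an amine oxidase of vessels, averaged 4.98 ± 0.80 and 8.10 ± 1.20 CPM (DESeq2 adjusted p = 0.0172). NPW, the neuropeptide W precursor, was called lower, at 9.29 ± 3.49 and 4.06 ± 1.05 CPM (DESeq2 adjusted p = 0.0423). On the simulated counts 28.9% of DESeq2 calls were unchanged genes. Those counts lacked the library axis of the real data, so the share among the real calls is not known. For COL4A6, COL27A1, AOC3 and NPW edgeR gave an adjusted p of 0.426.

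For other biology lists camera gave adjusted p = 0.884 for progestin and glucocorticoid responsive genes (10 of 17 higher), 0.527 for the circadian clock, 0.333 for thyroid hormone and tanycyte genes, 0.75 for feeding peptides, 0.913 for the interferon response and 0.471 for neurosteroid synthesis. Each of these 6 lists had 0 members passing, over all genes or adjusted over the list alone. The cold inducible and heat shock list had a median of 0.03 and a mean of -0.04, and the feeding list a median of -0.02 and a mean of 0.01, so that median and mean differed in sign.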
